A study of Homo sapiens with 96 samples.

How the data were processed

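RNA of 8 breast cancer cell lines was measured after 48 h or 120 h in DMSO or 30 nM PF-9363, with 3 libraries per group. Per the labels, libraries were made with a stranded poly(A) kit and read as 150 bp pairs. Per the submitters' processing notes, reads were aligned to GRCh38, counted with featureCounts and handled with edgeR 3.30.3 and limma 3.44.3. The table deposited by the authors held TPM, that is, counts scaled for gene length and library size, for 18670 gene symbols in 96 libraries. Counts were not used here. The values of a library summed to 60.74 to 91.62% of the full TPM total, which leaves part of the total outside the table. No symbol holds a hyphen, so HLA and mitochondrially encoded genes are absent. T47D, ZR751 and MCF7 are given at full precision and the other 5 lines to 2 decimals. Of the symbols, 18498 are in GENCODE 29, 18468 of them protein coding, and 172 are not. TPM carries no depth, so the counting error of a gene cannot be given, and the spread between libraries is the only measure of precision here.

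All 96 libraries were kept and correlated best with one of their own line, 94 with one of their group, and no pair was identical. The labels give no pairing, so the 3 libraries of a group were unpaired replicates. In 0 of 16 contrasts did deviations from group means correlate over 0.1 in every same-number pair. In T47D and ZR751 at 120 h each library matched its own number best. Each line's 12 libraries were fitted together by limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(TPM + 1), with 4 group means, 8 residual degrees of freedom and empirical Bayes moderation with trend and robust options. Genes with a mean of at least 1 TPM over the line's libraries were tested. Inhibitor was set against DMSO at each time, which made 16 contrasts, and the changes of the 2 times against each other. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and genes with an adjusted p under 0.05 are called. A change of at least 2-fold means a log2 change of at least 1. Each line has its own spread in these fits. Differences between lines were tested by limma's F test in 1 fit of all 96 libraries, over genes that passed the filter in at least 1 line.

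Gene lists were written before the data were examined, as were the tests, the receptor classes, the rule for named genes and most alternatives. There were 22 lists, of which 21 were tested, since the table holds none of the mitochondrially encoded genes. They cover KAT6 complexes and other MYST acetyltransferases, other acetyltransferases and deacetylases, oestrogen receptor targets, luminal, basal and mesenchymal genes, DNA replication, mitosis, CDK inhibitors, p53 targets, apoptosis regulators and HOX genes. The others are MYC and ribosome biogenesis, interferon-stimulated, antigen presentation (10 of 20 in the table), sterol biosynthesis, unfolded protein and amino acid response, hypoxia and glycolysis, stromal and blood cell markers, histone genes (18 of 36 names in the table) and ribosomal proteins. Lists with at least 3 tested members were tested with camera of limma, two-sided, with its preset correlation of 0.01 and, beside it, a correlation estimated from the data. Adjustment was over all 334 list tests. Members were also counted with p-values adjusted over the list alone. Classes of lines and correlations across lines were tested by two-sided exact permutation.

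The rule for named genes took KAT6A, KAT6B and ESR1 in every line. Per line it took the 8 called genes that rose most and the 8 that fell most at 120 h, and the 4 and 4 at 48 h. These needed a mean of at least 5 TPM in 1 group and no overlap of the libraries of the groups. It also took the 12 genes called higher and the 12 called lower in the most lines, up to 4 called members of each list, and 10 fixed members of lists. The text names part of these, chosen after values were seen. Most top genes of a line whose call ended without some library are named only with the alternatives. Other such genes are mostly unmarked. Symbols with close paralogs or pseudogenes are uncertain, since reads shared between copies cannot be told apart in TPM.

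The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, each library rescaled to the same sum, a replicate block, only the 6 libraries of a contrast, all 96 libraries in 1 fit and leaving out each library in turn. For the lines, YMB1 was left out. For the gene lists, leaving out each library was added after the data were seen. Counts were called moved when they changed by over 1.5 times. The fit was tested on simulated data with each line's own spread, in which 100 genes were changed by log2 0.5 and 100 by log2 1. At 120 h limma found 91 and 97 of them in T47D, 87 and 96 in ZR751, 69 and 97 in MCF7, 69 and 98 in CAMA1, 57 and 90 in YMB1, 47 and 92 in HCC1187, 66 and 95 in HCC1954 and 32 and 85 in DU4475, with 6 to 12 false calls per line. With no gene changed it made 0 calls in each line. Of 200 random lists of unchanged simulated genes, camera gave a p under 0.05 for 1 in T47D and 5 in DU4475. The simulated spread was drawn for each gene on its own. These lists therefore do not show how camera behaves on lists of correlated genes. For the line difference, 188 of 200 changed genes were found with 6 false calls when the lines shared 1 spread, and 197 with 166 false calls when each had its own.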

Results

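Poly(A)-selected RNA from 8 human breast cancer cell lines was sequenced after culture with 30 nM PF-9363 (also called CTx-648), a selective inhibitor of the histone acetyltransferases KAT6A and KAT6B, or with its solvent DMSO. The lines were T47D, ZR751, MCF7, CAMA1, YMB1, DU4475, HCC1187 and HCC1954. Each line was sampled at 48 h (2 days) and 120 h (5 days) in triplicate, which made 32 groups of 3 libraries and 96 libraries. The deposited table held TPM of 18670 gene symbols. TPM keeps no sequencing depth, so the depth of each library is unknown here and no counting error can be given. Between 11174 and 12039 genes per library reached 1 TPM, and the lowest correlation of log2(TPM + 1) between libraries of 1 group was 0.9888. The labels do not say whether the triplicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Levels are given as mean TPM ± SD (n = 3 per group) and changes as log2 fold changes of TPM + 1, inhibitor against DMSO, which understate the change of low genes.

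KAT6A and KAT6B, the targets of the compound, kept similar transcript levels in most contrasts. KAT6A (GRCh38 chromosome 8, 41929479 to 42052026) ranged in DMSO at 120 h from 7.45 ± 0.289 TPM in MCF7 to 61.5 ± 0.819 in CAMA1. It passed the test in 1 of the 16 contrasts, in ZR751 at 120 h, where it fell from 21.1 ± 0.477 to 18.6 ± 1.17 TPM (log2 -0.17 ± 0.05 SE, adjusted p = 0.00811). In HCC1187 at 120 h the KAT6A change of -0.31 had an adjusted p of 0.104, which became 0.00751 (log2 -0.50) without inhibitor replicate 3. KAT6B (chromosome 10, 74824927 to 75032624) rose in T47D at 48 h (0.20, adjusted p = 0.0108) and 120 h (0.19, 0.00936). It also rose in HCC1187 at 48 h (0.38, 0.0165), in CAMA1 at 48 h (0.19, 0.0435) and in YMB1 at 120 h (0.22, 0.0296). Those last 3 calls were less firm. In HCC1187 the call ended without DMSO replicate 2 (adjusted p = 0.0638) or 3 (0.0576), in CAMA1 without any 1 of the 6 libraries (0.0505 to 0.147), and in YMB1 without any 1 except inhibitor replicate 3 (0.0516 to 0.119).

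ESR1, which encodes oestrogen receptor alpha (chromosome 6, 151656691 to 152129619), fell in T47D, ZR751, MCF7 and CAMA1 at both times. At 120 h it went from 6.29 ± 0.362 to 3.37 ± 0.192 TPM in T47D (log2 -0.74 ± 0.05 SE, adjusted p = 1.22e-06) and from 3.23 ± 0.105 to 0.883 ± 0.0494 TPM in ZR751 (-1.17 ± 0.05, 5.36e-10). In MCF7 it went from 11.3 ± 0.219 to 6.24 ± 0.567 TPM (-0.77 ± 0.12, 0.000985) and in CAMA1 from 38.0 ± 1.27 to 29.6 ± 1.74 TPM (-0.35 ± 0.07, 0.00498). At 48 h the log2 changes were -0.79 in T47D, -1.14 in ZR751, -0.75 in MCF7 and -0.30 in CAMA1, with adjusted p of 3.08e-06, 2.78e-09, 0.00249 and 0.00999. All 3 inhibitor libraries lay below all 3 DMSO libraries in each of these 8 contrasts, and each call held without any 1 of the 6 libraries. In HCC1187 and HCC1954 the change did not pass the test at either time, with adjusted p from 0.216 to 0.962. YMB1 had 0.560 ± 0.0917 TPM of ESR1 in DMSO and 1.42 ± 0.289 with the inhibitor at 120 h, and DU4475 had 0.0267 ± 0.00577 and 0.0767 ± 0.0551. Both lay below the filter of a mean of 1 TPM and were not tested. The ESR1 change differed between lines at 48 h (limma F test, F = 31.8, adjusted p = 3e-17) and at 120 h (F = 31.8, adjusted p = 6e-18).

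**Figure D1:**
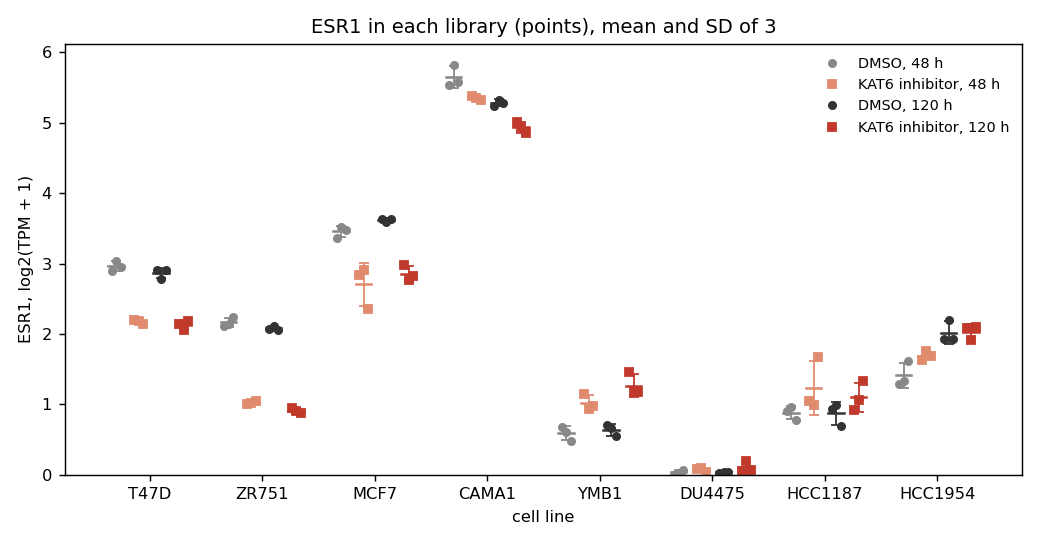
ESR1 level, log2(TPM + 1), in each library of the 8 lines at 48 h and 120 h, with points for single libraries and bars for the group mean and SD (n = 3). Inhibitor libraries lie below DMSO libraries in T47D, ZR751, MCF7 and CAMA1, where the log2 change at 120 h was -0.74, -1.17, -0.77 and -0.35.

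In T47D, S100A8 and S100A9, the subunits of the calcium-binding protein calprotectin, rose at 120 h from 15.4 ± 1.08 to 111 ± 1.19 TPM (log2 2.77 ± 0.11 SE, adjusted p = 1.52e-08) and from 27.2 ± 0.759 to 129 ± 9.68 TPM. KRT4, a keratin of mucosal epithelia, rose from 13.7 ± 1.38 to 51.0 ± 5.26 TPM, and CASP14, a caspase of epidermal differentiation, rose by 2.13. TFF3, a secreted trefoil peptide, fell from 128 ± 3.95 to 27.4 ± 3.81 TPM (-2.20 ± 0.08, adjusted p = 1.23e-08). The secreted matrix protein gene CTGF (-2.19), the connexin gene GJA1 (-1.96), the adhesion receptor gene MCAM (-1.79) and the metalloproteinase inhibitor gene TIMP1 (-1.69) also fell. By 48 h CYP1A1, a xenobiotic-metabolising enzyme, had risen by 1.80, and the falls included those of CTGF (-1.27), FGFBP2 (-1.23) and KRT13 (-1.18). At 48 h 2472 of 11699 tested genes passed the test (1656 higher, 816 lower), and 18 of them changed at least 2-fold. At 120 h 3902 passed (1682 higher, 2220 lower), and 94 changed at least 2-fold (34 up, 60 down). In 1 fit of all 96 libraries, 561 at 48 h and 1328 at 120 h passed, and with a pseudocount of 0.1, 45 at 48 h and 165 at 120 h changed at least 2-fold.

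Of the 39 tested oestrogen receptor target genes, 28 fell and 1 rose at 48 h in T47D (1 higher and 33 lower adjusted over the list alone; mean log2 -0.37, adjusted p = 4.38e-27, adjusted p = 0.027 with an estimated correlation). At 120 h 28 fell and 0 rose (30 lower adjusted over the list alone), led by TFF3 (-2.20), EGR3 (-1.72), WISP2 (-1.41) and RAPGEFL1 (-1.11). The mean log2 change was -0.52 (adjusted p = 5.37e-15; adjusted p = 0.0867 with an estimated correlation). Mitosis genes fell together at 120 h, 29 of 32 (30 lower adjusted over the list alone; mean log2 -0.23, adjusted p = 2.18e-12, adjusted p = 0.19 with an estimated correlation), with small changes such as KIF2C (-0.37), UBE2C (-0.34) and PLK1 (-0.34). Of 22 tested HOX genes, which encode positional transcription factors, 9 fell and 1 rose at 120 h (1 higher and 10 lower adjusted over the list alone; mean log2 -0.26, adjusted p = 0.00464, adjusted p = 0.163 with an estimated correlation), among them HOXB9 (-0.90), HOXD12 (0.87) and HOXA11 (-0.74). Of 10 basal and myoepithelial genes, 8 fell and 1 rose (1 higher and 9 lower adjusted over the list alone; mean log2 -0.24, adjusted p = 0.00569, adjusted p = 0.189 with an estimated correlation), including ACTA2 (-0.63) and ITGA6 (-0.44). The split of higher and lower genes depended on scaling: at 48 h it was 1147 higher and 1273 lower under median-ratio scaling and 1143 higher and 1104 lower under quantile normalization, and at 120 h it was 2360 higher and 1603 lower with each library rescaled to the same sum and 2078 higher and 1999 lower under quantile normalization.

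ZR751 had the most called genes of the 8 lines at both times. CDKN2B, which encodes the CDK4 and CDK6 inhibitor p15, rose at 120 h from 6.72 ± 0.916 to 377 ± 18.9 TPM (log2 5.62 ± 0.09 SE, adjusted p = 3.09e-13). The cornified envelope gene SPRR3 rose from 4.31 ± 1.28 to 139 ± 15.5 TPM, the adhesion receptor gene ADGRF1 from 1.60 ± 0.387 to 52.7 ± 1.21 TPM, and SERPINE1, the plasminogen activator inhibitor, from 1.18 ± 0.490 to 32.7 ± 2.56 TPM. EGR3, an oestrogen-induced transcription factor, fell from 29.4 ± 4.63 to 0.279 ± 0.135 TPM (-4.57 ± 0.11, adjusted p = 1.06e-11). The mammary secretoglobins SCGB2A2 and SCGB1D2 fell from 1753 ± 154 to 184 ± 5.66 and from 403 ± 26.2 to 29.5 ± 1.45 TPM. The stathmin family gene STMN3 (-3.84), the alpha-2A adrenergic receptor gene ADRA2A (-3.60) and the neuropeptide gene GAL (-3.31) fell as well. Large changes at 48 h included those of ADGRF1 (3.28), SERPINE1 (3.04), EGR3 (-3.67) and NXPH3 (-2.77). At 48 h 7036 of 11813 tested genes passed the test (4221 higher, 2815 lower), and 363 of them changed at least 2-fold. At 120 h 8344 passed (5009 higher, 3335 lower), and 1072 changed at least 2-fold (604 up, 468 down). With a pseudocount of 0.1, 548 at 48 h changed at least 2-fold.

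Cell cycle genes of ZR751 fell nearly as a block. All 32 mitosis genes fell at 120 h (32 lower adjusted over the list alone; mean log2 -1.40, adjusted p = 5.65e-19, adjusted p = 0.213 with an estimated correlation), among them AURKB (-1.75), PTTG1 (-1.75), AURKA (-1.74) and UBE2C (-1.73). All 35 tested DNA replication genes fell at 120 h (35 lower adjusted over the list alone; mean log2 -1.06, adjusted p = 1.71e-18, adjusted p = 0.138 with an estimated correlation). These included RRM2 (-1.58), CDC6 (-1.55) and GINS4 (-1.51). At 48 h 31 of 32 mitosis genes (adjusted p = 0.282 with an estimated correlation) and 35 of 35 replication genes (adjusted p = 0.138 with an estimated correlation) had fallen, and the counts were 31 and 35 adjusted over the list alone. Oestrogen receptor target genes fell in 35 of 39 cases and rose in 3 at 120 h (3 higher and 35 lower adjusted over the list alone; mean log2 -1.28, adjusted p = 2.46e-15, adjusted p = 0.0723 with an estimated correlation), including EGR3 (-4.57), GREB1 (-3.10), PGR (-3.09) and WISP2 (-3.01). MYC, a transcription factor of growth genes, fell by 2.04, and 24 of 30 genes of its ribosome biogenesis list fell (3 higher and 24 lower adjusted over the list alone; mean log2 -0.40, adjusted p = 1.27e-06, adjusted p = 0.219 with an estimated correlation). Interferon-stimulated genes rose in 20 of 26 cases and fell in 1 (20 higher and 1 lower adjusted over the list alone; mean log2 1.32, adjusted p = 3.17e-05, adjusted p = 0.308 with an estimated correlation). Examples were IFIT2 (2.99), IFI44 (2.86), OAS1 (2.74) and RSAD2 (2.56).

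Antigen presentation genes, of which the table holds no HLA gene, rose in ZR751 in 7 of 8 cases at 120 h (7 higher adjusted over the list alone; mean log2 1.02, adjusted p = 0.00156, adjusted p = 0.245 with an estimated correlation), led by the immunoproteasome subunits PSMB10 (1.81) and PSMB8 (1.69). Apoptosis regulators rose in 16 of 21 cases and fell in 2 (16 higher and 2 lower adjusted over the list alone; mean log2 0.50, adjusted p = 0.0172, adjusted p = 0.266 with an estimated correlation). They included the pro-apoptotic BMF (2.91), the inhibitor of apoptosis BIRC3 (1.89) and the anti-apoptotic BCL2 (-0.96). Of 22 p53 target genes 15 rose and 4 fell (15 higher and 4 lower adjusted over the list alone; mean log2 0.49, adjusted p = 0.0144, adjusted p = 0.319 with an estimated correlation). They included TP53I3 (1.60), TP53INP1 (1.54) and GDF15 (1.33). Sterol biosynthesis genes fell in 20 of 24 cases and rose in 2 (2 higher and 20 lower adjusted over the list alone; mean log2 -0.46, adjusted p = 2.66e-06, adjusted p = 0.11 with an estimated correlation). Among them were STARD4 (-1.49), LSS (-1.44) and INSIG1 (-1.03). Under quantile normalization the split of genes was 3563 higher and 3578 lower at 48 h and 4130 higher and 4244 lower at 120 h. Of genes changed at least 2-fold at 120 h, 538 were higher and 528 lower under median-ratio scaling and 510 were higher and 543 lower under quantile normalization.

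MCF7 was marked by the rise of interferon-stimulated genes. At 120 h IFI27 rose from 4.89 ± 0.730 to 54.4 ± 4.34 TPM (log2 3.24 ± 0.11 SE, adjusted p = 4.74e-09), IFI6 from 17.5 ± 3.51 to 135 ± 7.23 TPM, and OAS1, an antiviral oligoadenylate synthetase, from 0.963 ± 0.0602 to 11.6 ± 0.503 TPM. The crosslinking enzyme gene TGM2 (2.78), the calcium-binding protein gene S100A9 (2.60) and the hair keratin gene KRT81 (2.56) also rose. The collagen gene COL3A1 fell from 25.5 ± 0.757 to 7.13 ± 0.155 TPM (-1.70 ± 0.06, adjusted p = 7.39e-09). So did CYP26B1, which degrades retinoic acid (-1.77), the receptor-modifying protein gene RAMP3 (-1.50), the disulfide isomerase family gene AGR3 (-1.45) and the relaxin gene RLN2 (-1.36). By 48 h the hair keratin gene KRT85 rose from 0.270 ± 0.136 to 16.9 ± 4.79 TPM, and the repressor gene ZBTB18 rose by 1.70. The progesterone receptor gene PGR (-0.85), the homeobox gene IRX5 (-0.89) and the proteoglycan gene VCAN (-0.90) fell. At 48 h 1497 of 11655 tested genes passed the test (883 higher, 614 lower), and 23 of them changed at least 2-fold. At 120 h 2153 passed (1481 higher, 672 lower), and 159 changed at least 2-fold (145 up, 14 down). With only the 6 libraries of a contrast, 421 at 48 h and 3317 at 120 h passed, and with a pseudocount of 0.1, 63 at 48 h and 242 at 120 h changed at least 2-fold. Inhibitor replicate 3 of 48 h correlated at 0.994 and 0.995 with the other 2 libraries of its group, which correlated at 0.998 with each other, and without it 2146 genes passed at 48 h.

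Of 24 tested interferon-stimulated genes, 15 rose at 48 h in MCF7 (18 higher adjusted over the list alone; mean log2 0.41, adjusted p = 7.54e-13, adjusted p = 0.0138 with an estimated correlation) and 22 at 120 h (23 higher adjusted over the list alone; mean log2 1.44, adjusted p = 1.09e-27, adjusted p = 0.00285 with an estimated correlation). Both calls held with the estimated correlation. Antigen presentation genes rose in 7 of 8 cases at 120 h (7 higher adjusted over the list alone; mean log2 0.50, adjusted p = 7.32e-06, adjusted p = 0.117 with an estimated correlation). These included TAP2 (1.07) and CD74 (0.88). Of 11 mesenchymal genes 8 rose and 1 fell (8 higher and 1 lower adjusted over the list alone; mean log2 0.53, adjusted p = 0.00196, adjusted p = 0.11 with an estimated correlation). Examples were SERPINE1 (1.35) and TGFBI (1.20). Basal genes rose in 8 of 14 cases and fell in 1 (8 higher and 2 lower adjusted over the list alone; mean log2 0.41, adjusted p = 0.00411, adjusted p = 0.173 with an estimated correlation), and luminal identity genes fell in 10 of 27 and rose in 5 (6 higher and 12 lower adjusted over the list alone; mean log2 -0.18, adjusted p = 0.00121, adjusted p = 0.138 with an estimated correlation). Oestrogen receptor target genes fell in 16 of 39 cases and rose in 1 at 48 h (2 higher and 18 lower adjusted over the list alone; mean log2 -0.18, adjusted p = 0.00262, adjusted p = 0.505 with an estimated correlation). At 120 h 11 fell and 9 rose (10 higher and 11 lower adjusted over the list alone; adjusted p = 0.373), so the list as a whole did not pass the test. The 48 h count fell to 778 without DMSO replicate 2 and to 883 without DMSO replicate 3, and 35 genes changed at least 2-fold without inhibitor replicate 1. The VCAN call ended without DMSO replicate 2 or 3 or inhibitor replicate 3 (highest adjusted p = 0.0948), and under quantile normalization the 120 h split was 1354 higher and 1420 lower. At 48 h the split was 713 higher and 1063 lower with all 96 libraries in 1 fit and 746 higher and 899 lower without inhibitor replicate 2, and the mean of the oestrogen receptor list was -0.11 without inhibitor replicate 3.

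In CAMA1 at 120 h the calcium-binding protein gene S100P fell from 34.9 ± 5.45 to 9.87 ± 0.639 TPM (log2 -1.71 ± 0.14 SE, adjusted p = 4.03e-06), the secretoglobin gene SCGB2A2 from 50.0 ± 2.26 to 15.4 ± 2.37 TPM, the breast mucin gene MUCL1 from 191 ± 11.2 to 88.1 ± 6.40 TPM and the breast antigen gene ANKRD30A from 97.0 ± 7.40 to 41.6 ± 1.08 TPM. The cytokine gene IL32 rose from 1.78 ± 0.676 to 8.21 ± 0.330 TPM (1.76 ± 0.20, adjusted p = 6.51e-05). The small GTPase gene ARL4D (1.33), the retroviral restriction factor TRIM5 (1.31), the transcription factor SALL2 (1.42) and the calcium-binding protein gene S100A1 (1.19) rose. By 48 h the stress cytokine gene GDF15 fell from 45.1 ± 0.921 to 11.6 ± 2.21 TPM and the netrin receptor gene UNC5B by 1.29, while the immunoproteasome subunit PSMB9 rose by 1.29. At 48 h 2188 of 11258 tested genes passed the test (1056 higher, 1132 lower), and 27 of them changed at least 2-fold. At 120 h 1823 passed (1125 higher, 698 lower), and 40 changed at least 2-fold (24 up, 16 down). With a pseudocount of 0.1, 81 at 48 h and 102 at 120 h changed at least 2-fold.

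The unfolded protein and amino acid response list fell in 14 of 24 genes and rose in 1 at 48 h in CAMA1 (1 higher and 15 lower adjusted over the list alone; mean log2 -0.29, adjusted p = 2.36e-09, adjusted p = 0.0122 with an estimated correlation). At 120 h 14 fell (17 lower adjusted over the list alone; mean log2 -0.23, adjusted p = 1.13e-12, adjusted p = 0.0058 with an estimated correlation), with the cystine transporter SLC7A11 (-0.86) and the serine synthesis enzyme PHGDH (-0.56). Both calls held with the estimated correlation. Mitosis genes fell in 31 of 32 cases at 48 h (32 lower adjusted over the list alone; mean log2 -0.56, adjusted p = 1.91e-23, adjusted p = 0.11 with an estimated correlation), with CDC20 (-0.89), KIF2C (-0.83), NEK2 (-0.83) and PLK1 (-0.79), and in 4 at 120 h (2 lower adjusted over the list alone; mean log2 -0.11, adjusted p = 0.000379, adjusted p = 0.455 with an estimated correlation). Oestrogen receptor target genes fell in 20 of 38 cases and rose in 5 at 48 h (7 higher and 21 lower adjusted over the list alone; mean log2 -0.21, adjusted p = 0.000125, adjusted p = 0.138 with an estimated correlation). At 120 h 17 fell and 3 rose (4 higher and 18 lower adjusted over the list alone; mean log2 -0.17, adjusted p = 4.47e-05, adjusted p = 0.138 with an estimated correlation). They included PDZK1 (-0.80), PGR (-0.70), CXCL12 (-0.64) and TFF1 (-0.62). CDKN1A, the p53 target that encodes p21, rose by 0.81 at 48 h and 0.86 at 120 h. Histone genes rose in 5 of 11 cases at 120 h (6 higher adjusted over the list alone; mean log2 0.31, adjusted p = 0.000411, adjusted p = 0.213 with an estimated correlation). At 120 h the split was 980 higher and 942 lower under median-ratio scaling and 919 higher and 922 lower under quantile normalization, and at 48 h it was 1478 higher and 929 lower with each library rescaled to the same sum. At 48 h it was 1162 higher and 1072 lower under quantile normalization and 932 higher and 855 lower without DMSO replicate 2. At 120 h the mean of the mitosis list was -0.06 without inhibitor replicate 3, and that of the histone list 0.49 with a pseudocount of 0.1. Of genes changed at least 2-fold at 120 h, 21 were higher and 17 lower under median-ratio scaling and 17 were higher and 19 lower under quantile normalization.

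In YMB1 PSCA, a surface antigen, rose at 120 h by 4.67 ± 0.12 SE (adjusted p = 4.69e-11). The prolactin-induced protein gene PIP rose from 22.4 ± 3.24 to 388 ± 19.1 TPM, the cell adhesion genes CEACAM6 from 3.50 ± 0.463 to 77.1 ± 2.36 and CEACAM5 from 4.53 ± 1.67 to 53.2 ± 2.79 TPM, and the keratinocyte calmodulin-like gene CALML5 by 3.78. HOXC6 fell from 18.0 ± 2.03 to 3.98 ± 1.47 TPM (-1.97 ± 0.25, adjusted p = 4.28e-05), as did the transcription factor genes PRRX2 (-2.43), HES7 (-2.37) and LHX9 (-2.22). At 48 h PSCA (2.69), the immediate early gene EGR1 (2.23) and the ketogenesis enzyme HMGCS2 (2.07) led the rises. CORO1A, an actin regulator (-2.06), and LHX9 (-1.82) led the falls. At 48 h 2844 of 11770 tested genes passed the test (1717 higher, 1127 lower), and 106 of them changed at least 2-fold. At 120 h 4317 passed (2230 higher, 2087 lower), and 343 changed at least 2-fold (201 up, 142 down). With a pseudocount of 0.1, 256 at 48 h and 574 at 120 h changed at least 2-fold.

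Mitosis genes fell in 31 of 32 cases at 48 h in YMB1 (32 lower adjusted over the list alone; mean log2 -0.59, adjusted p = 4.75e-22, adjusted p = 0.163 with an estimated correlation). Among them were AURKB (-0.79), UBE2C (-0.74), KIF2C (-0.74) and PLK1 (-0.72). At 120 h 22 fell (22 lower adjusted over the list alone; mean log2 -0.39, adjusted p = 7.97e-08, adjusted p = 0.39 with an estimated correlation). DNA replication genes fell in 20 of 36 cases at 48 h and rose in 1 (1 higher and 24 lower adjusted over the list alone; mean log2 -0.33, adjusted p = 2.8e-09, adjusted p = 0.226 with an estimated correlation), whereas at 120 h 2 fell and 3 rose (3 higher and 2 lower adjusted over the list alone; adjusted p = 0.708). Sterol biosynthesis genes rose in 15 of 24 cases and fell in 1 at 120 h (17 higher and 1 lower adjusted over the list alone; mean log2 0.34, adjusted p = 6.54e-06, adjusted p = 0.287 with an estimated correlation). These included SC5D (0.84), IDI1 (0.73) and ACAT2 (0.72). Mesenchymal genes fell in 6 of 7 cases (6 lower adjusted over the list alone; mean log2 -0.81, adjusted p = 0.000405, adjusted p = 0.127 with an estimated correlation). Examples were TWIST1 (-1.31), TGFB1 (-1.18) and SNAI1 (-0.89). HOX genes fell in 6 of 14 cases and rose in 1 (1 higher and 7 lower adjusted over the list alone; mean log2 -0.50, adjusted p = 0.0054, adjusted p = 0.39 with an estimated correlation). They included HOXC6 (-1.97), HOXC9 (-1.22) and HOXC4 (-1.08). Histone genes rose in 7 of 10 cases (8 higher adjusted over the list alone; mean log2 0.75, adjusted p = 0.000116, adjusted p = 0.189 with an estimated correlation). At 48 h the split was 1395 higher and 1414 lower under median-ratio scaling. At 120 h it was 2130 higher and 2238 lower under quantile normalization and 1696 higher and 1905 lower without inhibitor replicate 3.

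In HCC1187 the matrilysin gene MMP7 rose at 120 h from 7.41 ± 1.02 to 93.3 ± 2.08 TPM (log2 3.49 ± 0.10 SE, adjusted p = 2.48e-12) and the collagenase gene MMP1 from 5.76 ± 1.20 to 38.4 ± 2.58 TPM. UBD, an inflammation-induced ubiquitin-like modifier, rose from 4.64 ± 0.615 to 38.9 ± 2.00 TPM and the elastase inhibitor gene PI3 from 0.217 ± 0.0306 to 5.42 ± 0.272 TPM. The chemokine gene CCL19 fell from 101 ± 8.95 to 20.1 ± 3.43 TPM (-2.28 ± 0.13, adjusted p = 1.55e-08), the S100 protein gene S100A7 from 99.2 ± 16.6 to 31.5 ± 1.66 TPM, and the homeobox gene SIX2 from 21.3 ± 1.44 to 6.06 ± 0.942 TPM. By 48 h the immediate early genes FOS and FOSB rose from 32.9 ± 3.13 to 113 ± 17.9 and from 2.02 ± 0.748 to 9.60 ± 1.91 TPM, and the polyamine acetyltransferase SAT1 from 3.45 ± 0.156 to 14.0 ± 1.45 TPM. At 48 h 1476 of 11884 tested genes passed the test (893 higher, 583 lower), and 68 of them changed at least 2-fold. At 120 h 2971 passed (1034 higher, 1937 lower), and 220 changed at least 2-fold (180 up, 40 down). In 1 fit of all 96 libraries, 2845 at 48 h passed, and with a pseudocount of 0.1, 177 at 48 h and 377 at 120 h changed at least 2-fold. The CDK inhibitor gene CDKN2B rose by 2.04 at 120 h.

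DNA replication genes of HCC1187 fell in 21 of 36 cases at 48 h (22 lower adjusted over the list alone; mean log2 -0.30, adjusted p = 8.63e-15, adjusted p = 0.161 with an estimated correlation) and in 30 at 120 h (33 lower adjusted over the list alone; mean log2 -0.54, adjusted p = 1.65e-15, adjusted p = 0.151 with an estimated correlation). Among them were CCNE2 (-0.94), GINS2 (-0.90) and CDC6 (-0.81). Mitosis genes fell in 13 of 32 cases at 48 h (19 lower adjusted over the list alone; mean log2 -0.22, adjusted p = 1.16e-10, adjusted p = 0.219 with an estimated correlation) and in 30 at 120 h (31 lower adjusted over the list alone; mean log2 -0.48, adjusted p = 1.75e-14, adjusted p = 0.171 with an estimated correlation). These included KIF11 (-0.70), MKI67 (-0.66) and CCNB1 (-0.65). Interferon-stimulated genes rose in 12 of 32 cases and fell in 1 at 120 h (13 higher and 1 lower adjusted over the list alone; mean log2 0.29, adjusted p = 2.23e-06, adjusted p = 0.31 with an estimated correlation). Examples were IFITM1 (1.54), CXCL10 (1.11) and IFITM2 (0.86). Of 18 basal genes 6 rose and 2 fell (7 higher and 3 lower adjusted over the list alone; mean log2 0.28, adjusted p = 0.0115, adjusted p = 0.22 with an estimated correlation). They included CAV1 (1.32), KRT17 (1.30) and CDH3 (1.07). Mesenchymal genes went both ways, 5 of 10 higher and 3 lower (5 higher and 3 lower adjusted over the list alone; mean log2 0.28, adjusted p = 0.00411, adjusted p = 0.287 with an estimated correlation). They included the gelatinase gene MMP2 (-1.35) and the adhesion protein gene TGFBI (1.18). The 48 h count fell to 721 without DMSO replicate 2 and to 821 without DMSO replicate 3. At 120 h the split was 1567 higher and 1267 lower under median-ratio scaling and 1431 higher and 1560 lower under quantile normalization, and at 48 h it was 1228 higher and 446 lower with each library rescaled to the same sum. Without inhibitor replicate 3 it was 555 higher and 786 lower at 48 h, and with a pseudocount of 0.1 the mean of the mesenchymal list was 0.18.

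In HCC1954 at 120 h IFI44L rose from 9.32 ± 3.87 to 38.8 ± 12.2 TPM (log2 1.97 ± 0.29 SE, adjusted p = 0.00216), IFI6 from 50.2 ± 16.4 to 127 ± 13.8 TPM, OAS2 from 7.50 ± 3.16 to 21.6 ± 3.54 TPM and the ubiquitin-like modifier gene ISG15 from 44.7 ± 6.25 to 97.1 ± 15.7 TPM. The gelatinase gene MMP2 fell from 17.6 ± 1.06 to 5.32 ± 0.749 TPM (-1.56 ± 0.10, adjusted p = 3.67e-06) and the fibronectin gene FN1 from 109.9 ± 6.41 to 52.8 ± 10.4 TPM. The creatine kinase gene CKB fell by 0.99. At 48 h MMP2 (-1.04) and the collagenase gene MMP13 (-0.95) fell, and the GABA receptor subunit GABRP (0.99) and the repressor ZBTB18 (0.96) rose. At 48 h 799 of 11728 tested genes passed the test (551 higher, 248 lower), and 6 of them changed at least 2-fold. At 120 h 671 passed (416 higher, 255 lower), and 20 changed at least 2-fold (16 up, 4 down). In 1 fit of all 96 libraries, 1693 at 48 h and 1502 at 120 h passed, and with only the 6 libraries of a contrast, 265 at 120 h passed. With a pseudocount of 0.1, 37 at 48 h and 53 at 120 h changed at least 2-fold. Of 30 tested interferon-stimulated genes 22 rose at 120 h (26 higher and 1 lower adjusted over the list alone; mean log2 0.71, adjusted p = 3.11e-20, adjusted p = 0.127 with an estimated correlation). At 48 h limma called 0 members, with 7 at an unadjusted p under 0.05 and 0 adjusted over the list alone, although the list passed (mean log2 change 0.24, adjusted p = 0.00437; adjusted p = 0.558 with an estimated correlation). Mesenchymal genes fell in 5 of 14 cases at 120 h (7 lower adjusted over the list alone; mean log2 -0.35, adjusted p = 7.04e-07, adjusted p = 0.0723 with an estimated correlation), with TGFB1 (-0.52) beside MMP2 and FN1. Mitosis genes fell in 13 of 32 cases (27 lower adjusted over the list alone; mean log2 -0.31, adjusted p = 3.05e-20, adjusted p = 0.161 with an estimated correlation). Among them were CDC20 (-0.57), PRC1 (-0.50) and KIF20A (-0.48).

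The HCC1954 counts depended on single libraries and on scaling. At 48 h they were 480 and 139 without DMSO replicate 1 and 2, and 190, 185 and 287 without inhibitor replicate 1, 2 and 3, and 10 genes changed at least 2-fold without DMSO replicate 3. At 120 h they were 361, 372 and 246 without DMSO replicate 1, 2 and 3 and 409 without inhibitor replicate 1, which left 13 genes changed at least 2-fold. The split was 328 higher and 421 lower at 48 h and 322 higher and 398 lower at 120 h under median-ratio scaling, and 361 higher and 350 lower and 331 higher and 401 lower under quantile normalization.

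DU4475 had the fewest called genes of the 8 lines at both times when each line had its own spread. With all 96 libraries in 1 fit it had 1205 at 48 h and 2753 at 120 h, more than T47D with 561 and 1328. At 120 h the kisspeptin receptor gene KISS1R rose from 4.64 ± 0.457 to 19.0 ± 7.92 TPM (log2 1.76 ± 0.22 SE, adjusted p = 0.000847), the transcriptional corepressor CBFA2T3 from 2.64 ± 0.480 to 8.41 ± 0.418 TPM and the desmosome gene PKP1 from 4.83 ± 0.543 to 12.4 ± 1.17 TPM. The interleukin receptor gene IL21R fell from 5.93 ± 1.11 to 0.963 ± 0.218 TPM (-1.81 ± 0.21, adjusted p = 0.00084). The retinoic acid synthesis enzyme ALDH1A2 fell from 189.9 ± 12.6 to 78.3 ± 19.5 TPM, the guanosine monophosphate reductase GMPR from 7.05 ± 0.251 to 2.25 ± 0.0907 TPM and the asparagine synthetase ASNS from 176 ± 14.2 to 82.7 ± 19.2 TPM. At 48 h STARD3, a lipid transfer protein, fell from 901 ± 33.9 to 479 ± 19.5 TPM (-0.91 ± 0.09, adjusted p = 0.000429) and PKP1 rose by 1.03. At 48 h 31 of 11596 tested genes passed the test (19 higher, 12 lower), and 2 of them changed at least 2-fold. At 120 h 409 passed (272 higher, 137 lower), and 35 changed at least 2-fold (23 up, 12 down). In 1 fit of all 96 libraries, 14 at 48 h and 72 at 120 h changed at least 2-fold, and with only the 6 libraries of a contrast, 283 at 48 h and 38 at 120 h passed. With only the 6 libraries of a contrast, 8 at 48 h and 19 at 120 h changed at least 2-fold, and with a pseudocount of 0.1, 5 at 48 h and 69 at 120 h changed at least 2-fold. Of 24 unfolded protein and amino acid response genes 3 fell at 120 h, ASNS, SLC7A11 (-0.98) and ATF4 (-0.85) (7 lower adjusted over the list alone; mean log2 -0.36, adjusted p = 7.98e-08, adjusted p = 0.219 with an estimated correlation). Of 23 hypoxia and glycolysis genes limma called 0 at 48 h (0 adjusted over the list alone, 1 at an unadjusted p under 0.05) and 0 at 120 h (0 adjusted over the list alone, 8 unadjusted). As a list they had a mean log2 change of -0.32 at 48 h (adjusted p = 0.000672; adjusted p = 0.663 with an estimated correlation) and 0.88 at 120 h (adjusted p = 4.59e-07; adjusted p = 0.505 with an estimated correlation). Each of these list calls ended without 1 library. The 48 h mean was -0.02 (adjusted p = 0.429) without DMSO replicate 2 and -0.51 without DMSO replicate 3, and the 120 h mean was 0.34 (adjusted p = 0.0653) without inhibitor replicate 3. That library correlated at 0.9888 and 0.9909 with the other 2 of its group, which correlated at 0.9969 with each other.

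In DU4475 the median residual SD of log2(TPM + 1) was 0.164, the highest of the 8 lines, against 0.0632 in T47D. The 48 h count fell to 2 without DMSO replicate 1 or 2 or any 1 inhibitor replicate and to 6 without DMSO replicate 3. STARD3 and PKP1 kept their 48 h calls in each of these fits, and the other 6 genes named by the rule at 48 h lost theirs in at least 5 of the 6 fits. At 48 h 2 genes changed at least 2-fold, against 1 without DMSO replicate 1 or inhibitor replicate 1 or 2 and 0 without DMSO replicate 2 or inhibitor replicate 3. At 120 h the count was 78, 145 and 200 without DMSO replicate 1, 2 and 3, and 243 without inhibitor replicate 2, and 23 and 82 genes changed at least 2-fold without DMSO replicate 1 and inhibitor replicate 1. The ASNS call ended without DMSO replicate 1, 2 or 3 or inhibitor replicate 3 (highest adjusted p = 0.071). The splits at 48 h and 120 h were 32 higher and 36 lower and 285 higher and 324 lower under median-ratio scaling, 21 higher and 24 lower and 236 higher and 307 lower under quantile normalization, and 50 higher and 19 lower at 48 h with each library rescaled to the same sum.

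**Figure D2:**
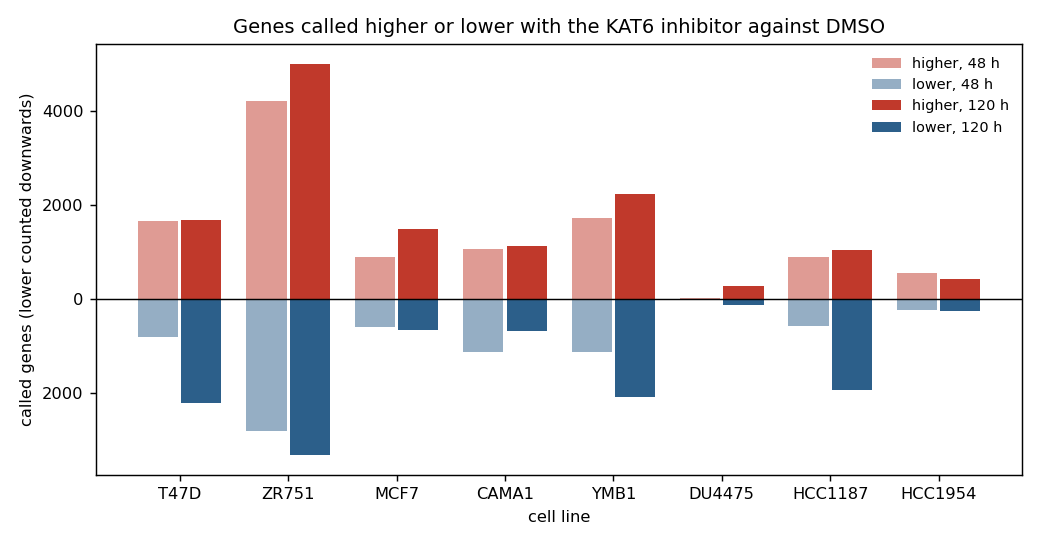
Number of genes called at an adjusted p under 0.05 in each line at 48 h and 120 h, with genes higher with the inhibitor drawn upward and genes lower drawn downward. ZR751 had the most at 120 h (5009 higher, 3335 lower) and DU4475 the fewest (272 higher, 137 lower).

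Across the 16 contrasts, the mitosis, DNA replication and oestrogen receptor lists were called, as whole lists, only lower and the interferon and histone lists only higher, while some single members of these lists were called the other way. By camera with its preset correlation, 126 of 334 list tests were called, 52 higher and 74 lower than other genes, and the mean, median and test had the same sign in each. Only 5 of the 126 held with an estimated correlation: oestrogen receptor genes in T47D at 48 h, interferon-stimulated genes in MCF7 and stress response genes in CAMA1 at both times. Mitosis genes were called lower in 12 contrasts, DNA replication genes in 9, oestrogen receptor genes in 7, unfolded protein and amino acid response genes in 8 and HOX genes in 6. Cytosolic ribosomal protein genes were called lower in 14 and higher in 1 (HCC1187 at 120 h), a call that ended without DMSO replicate 2, with the mean below 0 (adjusted p = 0.398), and without inhibitor replicate 1 (adjusted p = 0.108). The calls in DU4475 and HCC1187 at both times ended under quantile normalization. In ZR751 at 120 h 73 of 74 ribosomal protein genes fell (73 lower adjusted over the list alone; mean log2 -0.36, adjusted p = 2.51e-18, adjusted p = 0.332 with an estimated correlation), and in YMB1 70 fell (71 lower adjusted over the list alone; mean log2 -0.34, adjusted p = 8.22e-24, adjusted p = 0.138 with an estimated correlation). CAMA1 had 67 lower (71 lower adjusted over the list alone; mean log2 -0.19, adjusted p = 6.2e-44, adjusted p = 0.11 with an estimated correlation) and T47D 61 (67 lower adjusted over the list alone; mean log2 -0.13, adjusted p = 1.14e-14, adjusted p = 0.257 with an estimated correlation). Under quantile normalization the 120 h mean was -0.15 in YMB1, -0.12 in CAMA1 and -0.07 in T47D, and under median-ratio scaling it was -0.34, -0.21 and -0.12. Of the 126 called list tests, 19 lost their call without some single library.

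Interferon-stimulated genes were called higher in 12 of 16 contrasts, histone genes in 8, antigen presentation genes in 6 (lower in 1), apoptosis regulators in 5 and p53 target genes in 2. Other lists were called in either direction. Mesenchymal genes were higher in 5 and lower in 4, sterol biosynthesis genes in 4 and 4, and MYC and ribosome biogenesis genes in 2 and 4. Basal genes were higher in 3 and lower in 1, hypoxia and glycolysis genes in 2 and 2, and luminal identity genes in 1 and 1. The CDK inhibitors were called once, lower in HCC1954 at 120 h, with 1 of 7 members lower (3 lower adjusted over the list alone; mean log2 -0.23, adjusted p = 0.0289, adjusted p = 0.39 with an estimated correlation). That call ended without inhibitor replicate 1 (mean log2 -0.15, adjusted p = 0.115). The KAT6 complexes and other MYST acetyltransferases were called once, higher in DU4475 at 120 h (2 higher adjusted over the list alone; mean log2 0.22, adjusted p = 0.0104, adjusted p = 0.31 with an estimated correlation). The other acetyltransferases and deacetylases, with an adjusted p of 0.128 or more, and the stromal, endothelial and blood cell markers, with 0.236 or more in the 14 contrasts where at least 3 were tested, were not called. Among those markers in MCF7, the proteoglycan gene LUM rose (2.69) and COL3A1 fell at 120 h. Histone, ribosomal protein, CEACAM, OAS and IFIT genes have close copies, and how the authors' counting split reads between copies is not given, so single members are uncertain.

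**Figure D3:**
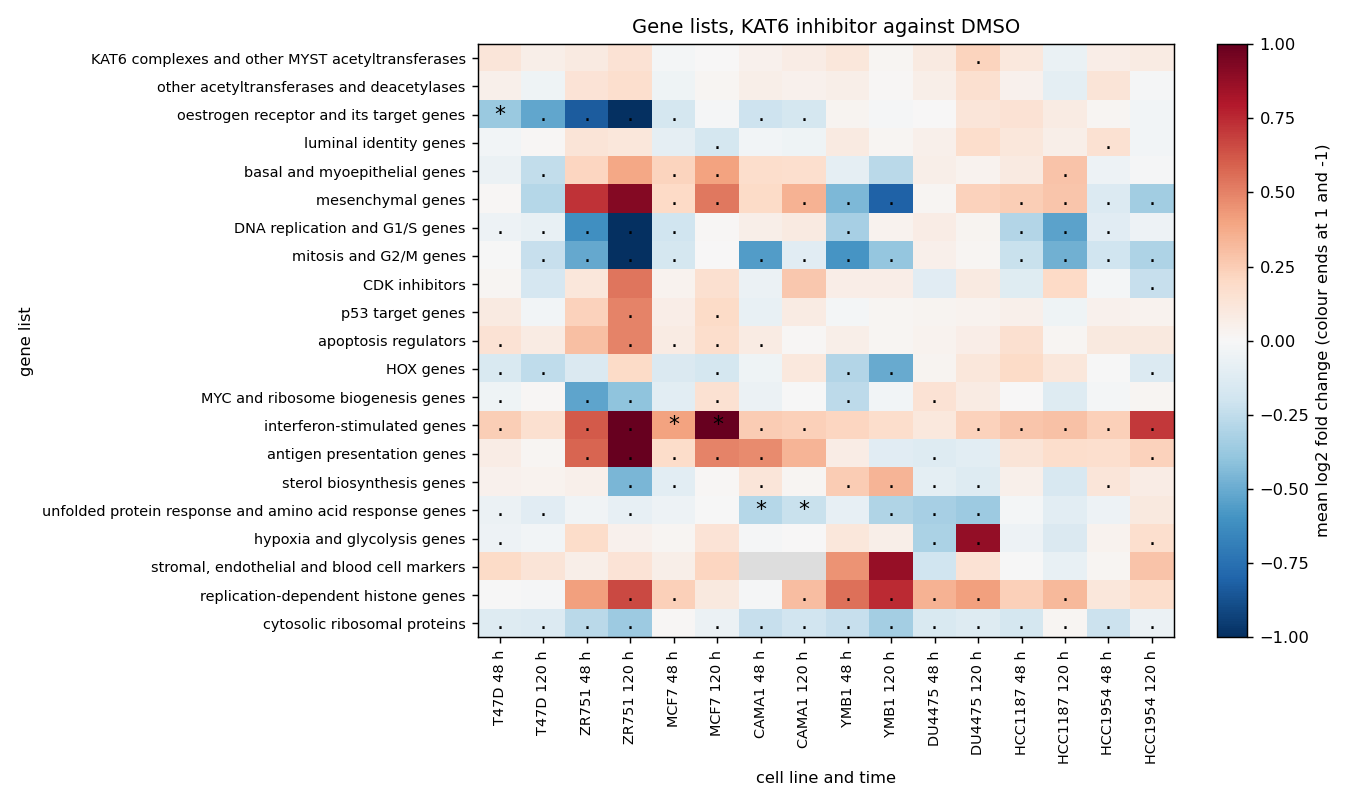
Mean log2 fold change of each gene list in each line at 48 h and 120 h, on a colour scale from -1 to 1, with a dot for lists called by camera with its preset correlation and a star for those also called with an estimated correlation. The 5 stars lie at the oestrogen receptor list in T47D at 48 h, the interferon list in MCF7 and the unfolded protein response list in CAMA1 at both times.

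Several genes changed in the same direction in most lines at 120 h. HIST1H2AC, a histone H2A gene, was higher in all 8 lines, with a mean log2 change over the 8 lines of 0.71 ± 0.51 (SD, n = 8). The histone gene HIST1H2BC (0.85 ± 0.59), the elastase inhibitor gene SERPINB1 (0.71 ± 0.59), the antigen-presenting molecule gene MR1 (0.65 ± 0.53), the major vault protein gene MVP (0.45 ± 0.42) and TMEM184A (0.44 ± 0.26) were higher in 7. Of the 40 genes higher in 6, the rule took the 6 with the largest mean, which were the protease inhibitor gene SLPI (1.04 ± 0.92), the polyamine acetyltransferase gene SAT1 (0.95 ± 0.83), TSPAN1 (0.90 ± 0.63), the TRAIL gene TNFSF10 (0.89 ± 0.70), the interferon signalling gene IRF9 (0.84 ± 0.88) and the pro-apoptotic gene BMF (0.78 ± 0.89). The homeobox gene IRX5 (-0.53 ± 0.33) and the histone deacetylase complex gene SAP30 (-0.48 ± 0.29) were lower in 7 lines. Of the 25 lower in 6 it took the 10 with the largest mean fall, which were MAST1 (-0.75 ± 0.61), PDZD4 (-0.72 ± 0.46), CERS1 (-0.71 ± 0.74), MAPK8IP2 (-0.66 ± 0.61), CDKN3 (-0.58 ± 0.51), SEPT3 (-0.51 ± 0.42), GPT2 (-0.50 ± 0.37), the mitochondrial folate enzyme gene MTHFD2 (-0.47 ± 0.44), the anaphase activator gene CDC20 (-0.44 ± 0.46) and the clock output gene DBP (-0.44 ± 0.28). None of these 24 was called the opposite way in any line at 120 h.

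**Figure D4:**
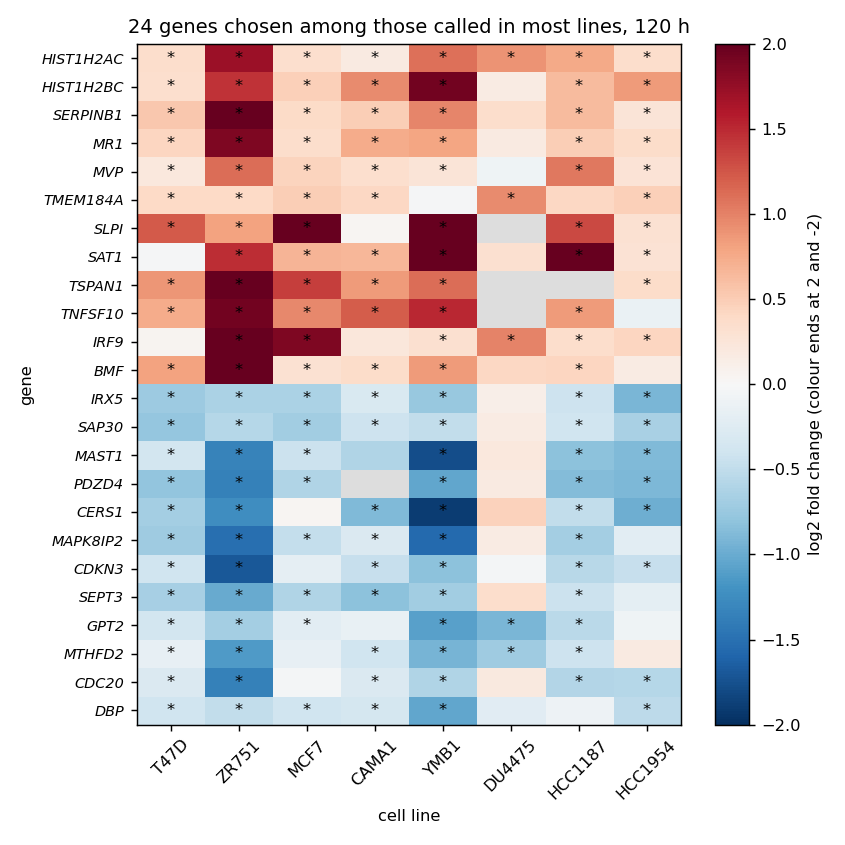
Log2 fold change at 120 h of 24 genes, by line, which were all those called in 1 direction in 7 or 8 lines and, of the 40 called higher and 25 lower in 6, the 6 and 10 with the largest mean changes, on a colour scale from -2 to 2, with a star where the gene was called and grey where it was not tested. HIST1H2AC has a star in all 8 lines, and IRX5 and SAP30 have one in 7.

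Of 14727 genes tested in at least 1 line, 3123 were called in no line at 120 h, 8920 in 1 direction only and 2684 higher in some lines and lower in others. The inhibitor effect differed between lines for 7364 genes (50% of those tested) at 48 h and 10415 (70.72%) at 120 h by limma's F test. HIST1H2AC, although higher in every line, was among them at 120 h (F = 34.1, adjusted p = 1.06e-18), as were BMF (F = 85.2, adjusted p = 1.54e-29) and SAT1 (F = 65.7, adjusted p = 2.67e-26). KAT6A was not (F = 1.84, adjusted p = 0.119). This fit gives all lines 1 spread. On simulated data with the spread of each line it made 166 false calls beside 197 of 200 changed genes found, so the counts hold some genes that differ only in spread.

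The early and late responses of a line were compared by the test of the difference itself. In ZR751 3088 genes changed differently at 120 h and 48 h. In T47D 481 did so (96 with a higher and 385 with a lower change at 120 h), in MCF7 547 (361 and 186), in YMB1 789 (297 and 492), in CAMA1 219 and in HCC1187 94. The splits depended on scaling: in T47D, MCF7 and YMB1 they were 161 and 177, 301 and 256, 411 and 412 under median-ratio scaling and 157 and 188, 370 and 391, 387 and 479 under quantile normalization. In HCC1954 there were 3, named here after their values were seen: the fibrinogen gene FGG (log2 difference 1.56, adjusted p = 0.00181), CASP14 (0.75, 0.00594) and S100A8 (0.80, 0.0146). In DU4475 limma called 0, with 652 genes at an unadjusted p under 0.05. Across genes, which are not independent replicates, the 48 h and 120 h log2 changes of a line correlated between r = 0.320 in HCC1954 (jackknife SD 0.156) and r = 0.867 in ZR751 (0.0108). Between lines at 120 h r was highest for ZR751 and YMB1 (0.459, jackknife SD 0.0369) and lowest for DU4475 and YMB1 (-0.0062, 0.102). In T47D 985 genes were higher and 691 lower at both times, against 238.1 and 154.8 for independent lists, and 17 were called in opposite directions. In ZR751 3630 were higher and 2326 lower at both times, against 1789.8 and 794.7, and 117 in opposite directions.

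Most of these time difference counts moved by over 1.5 times without some single library. In T47D they were 280, 301, 297 and 305 without DMSO replicate 1 or 3 or inhibitor replicate 2 or 3 of 48 h, and 256, 256 and 280 without DMSO replicate 1 or 2 or inhibitor replicate 1 of 120 h. In MCF7 they were 287 and 1144 without DMSO replicate 2 and inhibitor replicate 3 of 48 h. Leaving out a 120 h library of MCF7 gave 312, 313 and 345 for DMSO replicates 1, 2 and 3, and 284 and 338 for inhibitor replicates 1 and 3. In YMB1 they were 357 without inhibitor replicate 3 of 48 h, and 474, 326 and 499 without DMSO replicate 1 or 3 or inhibitor replicate 3 of 120 h. In HCC1187 the DMSO replicates 1, 2 and 3 gave 61, 37 and 39 when left out at 48 h and 59, 58 and 56 at 120 h, and the inhibitor replicates 32, 35 and 47 at 120 h. In CAMA1 they were 125, 118, 111 and 130 without DMSO or inhibitor replicates 2 and 3 of 48 h. Leaving out a 120 h library of CAMA1 gave 113 and 121 for DMSO replicates 2 and 3 and 145 and 127 for inhibitor replicates 1 and 2. In HCC1954 they were 5 without DMSO replicate 3 of 48 h or DMSO replicate 1 of 120 h, and 37 and 6 without inhibitor replicates 2 and 3 of 120 h. In 1 fit of all 96 libraries they were 97 in T47D, 1450 in ZR751, 1676 in YMB1, 440 in DU4475, 773 in HCC1187 and 427 in HCC1954.

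The lines were also compared by oestrogen receptor class, which the labels do not give. T47D, ZR751, MCF7, CAMA1 and YMB1 are widely described as receptor positive and DU4475, HCC1187 and HCC1954 as negative. YMB1 had 0.560 TPM of ESR1 in DMSO at 120 h, below HCC1954 with 3.06 and HCC1187 with 0.837. The ESR1 log2 change at 120 h averaged -0.48 ± 0.68 in the positive and 0.10 ± 0.11 in the negative lines (difference -0.58, exact permutation p = 0.1964, adjusted 0.9232), and at 48 h the difference was -0.74 (exact permutation p = 0.125, adjusted 0.4583). Called genes averaged 4108 ± 2602 against 1350.0 ± 1410.0 at 120 h (exact permutation p = 0.1607, adjusted 0.9232) and 3207 ± 2196 against 768.7 ± 723.0 at 48 h (exact permutation p = 0.07143, adjusted 0.4583). These counts also depend on the spread between the libraries of a line, so they do not compare the size of the responses alone. The median residual SD was 0.164 in DU4475, 0.138 in HCC1187 and 0.127 in HCC1954. In the positive lines it ran from 0.0632 in T47D to 0.126 in YMB1. The lowest p of the 22 values of each time was that of the HOX genes at 48 h (difference -0.22, exact permutation p = 0.01786, adjusted 0.3929) and of the ribosomal protein genes at 120 h (-0.16, exact permutation p = 0.08929, adjusted 0.9232). No value passed after adjustment over the 22 of its time. The tests were two-sided over 56 splits of the 8 lines, which allow no p under 0.0179, so a single value could not have passed that adjustment and these tests do not show that the classes were alike. T47D, ZR751 and MCF7, all in the positive class, were written with full precision and the other 5 lines to 2 decimals. Within those 5 the ESR1 difference was 0.04 at 120 h (exact p = 0.9) and -0.16 at 48 h (exact p = 0.7), and the called gene difference 1720.0 (exact p = 0.3) and 1747 (exact p = 0.2), where 10 splits allow no p under 0.1.

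The KAT6A level of each line was set against its number of called genes. That number depends on the spread between the libraries of a line as well as on its response. Across the 8 lines, the mean log2(TPM + 1) of KAT6A in DMSO at 120 h and the number of genes called at 120 h had Pearson r = -0.1235 (two-sided exact permutation p = 0.758) and Spearman rho = -0.1429 (exact permutation p = 0.752), and the adjusted p of both was 0.758. Without CAMA1 and MCF7, the 2 lines farthest from the median level, r was -0.2217 (exact p = 0.7). Levels of lines written in the 2 number formats were set side by side here. Within the 5 lines written to 2 decimals r was 0.0419 (exact p = 0.9333), and at 48 h over the 8 lines it was 0.03933 (exact p = 0.9084). The other 3 lines have 6 orderings, which allow no p under 0.05.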

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

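Of the tests of other splits in this part, those that exchange treatment labels for the time difference were run only after the result of those that exchange time labels was seen, although they were the plan on record, and those with the mean effects removed were chosen only after both results were seen. The results here were picked out because the effect of the inhibitor differed between times or between lines by a test of the difference itself. Between 48 h and 120 h, 481 genes differed in T47D, 3088 genes differed in ZR751, 547 genes differed in MCF7, 789 genes differed in YMB1, 94 genes differed in HCC1187, 3 genes differed in HCC1954 and 219 genes differed in CAMA1. Exchanged labels leave the effect of time or of the inhibitor in the difference, so those 2 kinds of split point to a structure of the samples and cannot decide about chance. Splits of the time labels within each treatment with as many genes or more, the real one included, numbered 2 of 100 in T47D, 5 of 100 in ZR751, 6 of 100 in MCF7, 7 of 100 in YMB1, 12 of 100 in HCC1187, 7 of 100 in HCC1954, 6 of 100 in CAMA1 and 100 of 100 in DU4475, and the highest counts of the others were 5403 in T47D, 6117 in ZR751, 4612 in MCF7, 3731 in YMB1, 1134 in HCC1187, 8066 in HCC1954, 4860 in CAMA1 and 1 in DU4475. Splits of the treatment labels within each time numbered 6 of 100 in T47D, 6 of 100 in ZR751, 6 of 100 in MCF7, 6 of 100 in YMB1, 7 of 100 in HCC1187, 6 of 100 in HCC1954, 7 of 100 in CAMA1 and 100 of 100 in DU4475, and the highest counts of the others were 1918 in T47D, 6077 in ZR751, 1229 in MCF7, 1814 in YMB1, 1744 in HCC1187, 223 in HCC1954, 438 in CAMA1 and 49 in DU4475.

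After the mean effects of the inhibitor and of time in a line were removed from each gene, splits of the treatment labels within each time with as many genes or more numbered 1 of 100 in T47D, 1 of 100 in ZR751, 1 of 100 in MCF7, 1 of 100 in YMB1, 1 of 100 in HCC1187, 2 of 100 in HCC1954, 1 of 100 in CAMA1 and 100 of 100 in DU4475, the real one included. The highest counts of the other splits were 2 in T47D, 1 in ZR751, 1 in MCF7, 1 in YMB1, 12 in HCC1187, 15 in HCC1954, 1 in CAMA1 and 220 in DU4475. By these splits chance between libraries, which may share a culture, was excluded except in HCC1954 and DU4475. In HCC1954 the real count was 3, and another split gave 15, which points to a structure of its samples. The same holds for DU4475, where limma called 0 with 652 at an unadjusted p under 0.05.

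Between lines the effect differed for 7364 genes at 48 h and 10415 at 120 h. Of 100 splits of the treatment labels within each line, 1 gave as many at 48 h and 1 at 120 h, the real one, and the highest of the others gave 1293 and 5573. These splits also left the effect of the inhibitor in the values, and none were run with it removed, so they cannot decide about chance.

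The 6 libraries of a contrast make 10 splits, too few for a share under 0.05. In each of the 16 contrasts 1 of 10 splits, the real one, gave as many called genes, and 1 of 10 as many genes changed at least 2-fold. The real counts ran from 31 called and 2 changed at least 2-fold in DU4475 at 48 h to 8344 and 1072 in ZR751 at 120 h. The highest called count of another split was 71 in DU4475 at 120 h (real 409), where 4 genes changed at least 2-fold (real 35). It was 1 in T47D at 120 h (real 3902) and in HCC1954 at 120 h (real 671), and 0 by limma in the other 13.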

How the results depend on the processing

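The receptor class within the 5 lines written to 2 decimals, and the KAT6A correlation without the 2 lines farthest from the median, were tests chosen only after the data were seen, as were the KAT6A correlation within those 5 lines and the gene lists without each library. No named gene turned to the other sign with a call on either side. The ESR1 difference between receptor classes at 120 h turned from -0.5819 to 0.03504 within the 5 lines, and the KAT6A correlation from -0.1235 to 0.03933 at 48 h and 0.0419 within the 5 lines, and none of these passed its test. The ribosomal protein list of MCF7 at 48 h went from a mean of 0.01078 (adjusted p = 0.211) to -0.01568 (adjusted p = 0.0477) without inhibitor replicate 3, and ranged up to 0.02531 without another library. The split of called genes turned to the other side in some contrasts, as given with the lines. Counts within 1.5 times of those reported are not repeated, and the cause was not tested for those that moved, except that fewer genes tested or libraries used are part of some settings. Depth is unknown, so nothing here shows what deeper sequencing would change. Of 1576 named results, the call ended for 182 with all 96 libraries in 1 fit, 152 with only the 6 libraries (where 1408 kept their side of the threshold and 8 gained a call), 124 with no filter, 73 under quantile normalization, 54 under median-ratio scaling, 24 with rescaling to the same sum and 11 with a pseudocount of 0.1. A mean TPM of at least 5 left part of the named results untested, and of the others 1340 kept their side of the threshold, 2 gained a call and 1 lost it. Leaving out 1 library ended a call in 1139 of 9444 fits of a named result, and 309 of 1379 called results lost their call in at least 1 of them. Of 126 called list tests 5 held with an estimated correlation, and calls ended for 9 under quantile normalization, 2 under median-ratio scaling and 1 with a pseudocount of 0.1, and 19 ended without some library. The line difference counts stayed within 1.5 times under the alternatives run, and the KAT6A correlation passed its test in none of them, including without YMB1. For the receptor class the alternatives say nothing about stability, since the splits of the lines are too few for a single value to pass.

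With all 96 libraries in 1 fit, called genes numbered 561 in T47D 48 h, 1328 in T47D 120 h, 1205 in DU4475 48 h, 2753 in DU4475 120 h, 2845 in HCC1187 48 h, 1693 in HCC1954 48 h and 1502 in HCC1954 120 h, and genes changed at least 2-fold numbered 14 in DU4475 48 h and 72 in DU4475 120 h, and time differences numbered 97 in T47D, 1450 in ZR751, 440 in DU4475, 1676 in YMB1, 773 in HCC1187 and 427 in HCC1954. With only the 6 libraries of a contrast, called genes numbered 421 in MCF7 48 h, 3317 in MCF7 120 h, 283 in DU4475 48 h, 38 in DU4475 120 h and 265 in HCC1954 120 h, and genes changed at least 2-fold numbered 8 in DU4475 48 h and 19 in DU4475 120 h. With median-ratio scaling, called genes numbered 68 in DU4475 48 h. With quantile normalization, called genes numbered 2435 in MCF7 48 h, and time differences numbered 144 in HCC1187. With each library rescaled to the same sum, called genes numbered 69 in DU4475 48 h and 643 in DU4475 120 h, and genes changed at least 2-fold numbered 46 in CAMA1 48 h, and time differences numbered 12 in HCC1954. With no filter, called genes numbered 6 in DU4475 48 h and 504 in HCC1954 48 h, and genes changed at least 2-fold numbered 1 in DU4475 48 h, and time differences numbered 61 in HCC1187. With a mean TPM of at least 5, genes changed at least 2-fold numbered 11 in T47D 48 h, 55 in T47D 120 h, 15 in MCF7 48 h, 101 in MCF7 120 h, 17 in DU4475 120 h, 216 in YMB1 120 h, 135 in HCC1187 120 h, 1 in HCC1954 48 h and 24 in CAMA1 120 h. With a pseudocount of 0.1, genes changed at least 2-fold numbered 45 in T47D 48 h, 165 in T47D 120 h, 548 in ZR751 48 h, 63 in MCF7 48 h, 242 in MCF7 120 h, 5 in DU4475 48 h, 69 in DU4475 120 h, 256 in YMB1 48 h, 574 in YMB1 120 h, 177 in HCC1187 48 h, 377 in HCC1187 120 h, 37 in HCC1954 48 h, 53 in HCC1954 120 h, 81 in CAMA1 48 h and 102 in CAMA1 120 h. The correlation of 48 h with 120 h moved to 0.6429 in T47D with a pseudocount of 0.1, 0.7451 in T47D with a mean TPM of at least 5 and 0.8881 in ZR751 with a mean TPM of at least 5.

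With a replicate block, called genes numbered 984 in MCF7 48 h, 5 in DU4475 48 h, 71 in DU4475 120 h, 422 in HCC1954 48 h and 361 in HCC1954 120 h, and time differences numbered 283 in T47D, 228 in MCF7, 465 in YMB1, 39 in HCC1187, 1 in HCC1954 and 94 in CAMA1. The block ended 146 named calls and 2 list calls.

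Leaving out 1 library at a time, called genes numbered 778 to 2146 in MCF7 48 h, 2 to 6 in DU4475 48 h, 78 to 482 in DU4475 120 h, 721 to 1341 in HCC1187 48 h, 139 to 596 in HCC1954 48 h and 246 to 631 in HCC1954 120 h, and genes changed at least 2-fold numbered 23 to 35 in MCF7 48 h, 0 to 2 in DU4475 48 h, 23 to 82 in DU4475 120 h, 5 to 10 in HCC1954 48 h and 13 to 27 in HCC1954 120 h, and time differences numbered 256 to 416 in T47D, 284 to 1144 in MCF7, 326 to 808 in YMB1, 32 to 70 in HCC1187, 2 to 37 in HCC1954 and 111 to 204 in CAMA1. Of the top genes of the lines, 20 lost their call without some library: SULT1A4 in T47D at 48 h; VCAN in MCF7 at 48 h; HSD11B2, GPA33, HSD17B4, CA6, GMPR and TMEM163 in DU4475 at 48 h; S100A4, PTPRH, ISLR, PSPH and ASNS in DU4475 at 120 h; BAALC in HCC1187 at 48 h; KCNB1 in HCC1187 at 120 h; ZACN and S100P in HCC1954 at 48 h; XAF1, ART3 and PBX3 in HCC1954 at 120 h.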

Other observations

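The 3 patterns weighed in this part were picked after the list results had been seen, and the tests of the histone genes were chosen only after the result was seen. Single regulators of the cell cycle went different ways between lines at 120 h. CCND1, which encodes cyclin D1, fell in T47D (-0.82, adjusted p = 1.04e-08) and CAMA1 (-0.59, adjusted p = 2.88e-05) and rose in ZR751 (0.25), HCC1187 (0.75) and DU4475 (0.61). CDKN1A, which encodes p21, rose in MCF7 (0.59), ZR751 (0.81), YMB1 (0.84) and CAMA1 (0.86). TFF1, an oestrogen-induced trefoil peptide, fell in ZR751 (-2.93) and CAMA1 (-0.62) but rose in MCF7 (0.53), where ESR1 and PGR (-0.84) fell. MYC fell in ZR751, YMB1 (-0.48) and CAMA1 (-0.13).

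Interferon-stimulated genes were higher as a list at 120 h in MCF7, ZR751 and HCC1954. With an estimated correlation the call held in MCF7 (adjusted p = 0.00285) and was lost in ZR751 (adjusted p = 0.308) and HCC1954 (adjusted p = 0.127). The tables argue against scaling of the libraries, since the lowest mean log2 change of the list in these lines under median-ratio scaling or quantile normalization was 0.6739. They also argue against 1 aberrant library, since at least 0.87 of the mean change stayed without any 1 library. A response of the cells to the inhibitor stays open as a hypothesis found on the same data, as do reads shared among close copies such as the OAS and IFIT genes, which were not tested.

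Ribosomal protein genes were lower as a list at both times in T47D, ZR751, YMB1 and CAMA1, and these calls were lost with an estimated correlation (adjusted p = 0.11 to 0.332). In 8 of 8 contrasts the mean of the list stayed more than 2 standard errors below 0 under both other scalings. This argues against scaling as the whole cause. In YMB1, T47D, CAMA1 and ZR751 the mean log2 change at 120 h was -0.34, -0.13, -0.19 and -0.36 as reported, -0.15, -0.07, -0.12 and -0.27 under quantile normalization and -0.34, -0.12, -0.21 and -0.44 under median-ratio scaling, and at 48 h it was -0.23, -0.13, -0.23 and -0.27, -0.12, -0.09, -0.12 and -0.20 and -0.28, -0.17, -0.23 and -0.32 in the same order. In 8 of 8 it lay below the lowest 2.5% of 1000 lists matched on transcript length and expression. This argues against a bias against short transcripts as the whole cause in these lines. At 120 h matched lists, less expressed, also fell on average in T47D and ZR751, not in YMB1 and CAMA1. Length from the longest and, after that result was seen, from the median protein-coding transcript gave 8 of 8 each. Reads shared with pseudogenes stay open, untested.

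Histone genes, most of whose transcripts have no poly(A) tail, had members called higher at 120 h in each line, from 2 to 9. The list as a whole was called higher at 120 h in ZR751, YMB1, HCC1187, CAMA1 and DU4475, where the call ended without DMSO or inhibitor replicate 2 (adjusted p = 0.087 and 0.0589), but not in T47D (adjusted p = 0.0778), MCF7 (0.541) or HCC1954 (0.117), and the 5 calls were lost with an estimated correlation (adjusted p = 0.163 to 0.213). In 3 of 8 lines a member was called lower (HIST1H1C in T47D, HIST2H2AC in ZR751 and HCC1187). In MCF7, CAMA1, YMB1, DU4475 and HCC1954 limma called 0 members lower, and the counts at an unadjusted p under 0.05 were 1, 0, 0, 1 and 1. RNA without poly(A) tails reaching the libraries of treated cells stays open in each line, and no biological explanation was tested.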
